A study of Mus musculus with 7 samples.

How the data were processed

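Reduced representation bisulfite sequencing (RRBS) was applied to genomic DNA of 7 mouse J1 embryonic stem cell libraries. RRBS cuts DNA with restriction enzymes, which enriches fragments rich in CpG dinucleotides, and bisulfite converts unmethylated cytosines so that each read reports whether a cytosine was methylated. Per the labels' protocols, the libraries used a double-enzyme digest and were sequenced on an Illumina instrument. Per the submitters' processing notes, cutadapt, Trim Galore and BSMAP 2.73 were used with the mouse build mm10. The order of these steps, the aligner settings, the program that called methylation and the test behind the deposited p-values are not given in the sources used here.

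The data came as 2 tables of single cytosine positions. The rescue table holds 18189 sites in 6 libraries (wild type, Uhrf1-/- and both rescues), and the knockdown table holds 21989 sites in the 2 wild-type libraries and the Mof knockdown. Per the file headers, the authors gave read counts per site and strand as total, methylated and unmethylated reads, and total reads equalled the sum of the others at every site. The deposited fraction of methylated reads per library is methylated over total reads and was recomputed here from the counts as a percent. The authors also listed a p-value and a q-value of each group against wild type and a difference in percentage points, which equalled the difference of reads pooled within each group. Every listed site had at least 5 reads in every library of its table. The sequence context of the cytosines is not named in the headers, so they are called sites here; 92 sites of the rescue table and 164 of the knockdown table also had the cytosine of the opposite strand listed. The tables share 12282 sites, at which the wild-type reads are identical, so the wild-type libraries of both tables are the same libraries. Tests were run within a table, except for the overlap of losses at shared sites.

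Groups were taken from the sample titles. The wild-type and Uhrf1-/- groups have 2 libraries each, and the wild-type rescue, the 3KR rescue and the Mof knockdown have 1 each. The rescue column ends in a digit that the labels do not explain. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The libraries of a group were not copies of each other: a chi-square of the reads averaged 2.85 per site and degree of freedom between the wild-type libraries and 2.17 between the Uhrf1-/- libraries, where sampling alone gives about 1.

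Library means were unweighted means of the site percentages over all sites of a table. A group with 2 libraries is given as mean ± SD. Where a standard error (SE) is given for a mean difference or for a share regained, it is a jackknife over the 19 autosomes, which covers the sampling of sites and not the spread between cultures. An exact permutation test of 2 against 2 libraries cannot give a p under 0.333, so library means were not tested. Wilson and exact binomial intervals of 95% cover counting error only, since the reads carry no molecular identifiers.

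Single sites were compared between Uhrf1-/- and wild type with edgeR's quasi-likelihood test on methylated and unmethylated counts, with the spread estimated over all libraries of the rescue table (edgeR 4.0.16, limma 3.58.1, R 4.3.3). A site had to have at least 10 reads in the 4 libraries compared, and was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 20 percentage points. Promoters were tested with edgeR on reads summed per gene. Named promoters were adjusted among genes with at least 3 sites of at least 10 reads. Gene-list members were adjusted among all promoters, with any number of sites of at least 5 reads. The promoter levels printed beside these p-values are unweighted means over sites. The single-library groups have no spread of their own, so a test of them must borrow the spread of the replicated groups; such tests were run as alternatives only. For these groups, sites that differed by at least 20 points, with at least 10 reads in each library compared, were counted beside the same count between replicate libraries. Fisher's exact test per site, two-sided and adjusted by the same method, was run between pairs of libraries and compares those libraries, not the conditions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest, and matplotlib 3.10.9 for the plots.

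The edgeR test was tested on simulated data with the reads, the levels and the replicate spread of the 4603 sites with enough reads for Uhrf1-/- against wild type. With 200 changed sites it recovered 0 of 50 at each of 20, 40 and 60 points and 4 of 50 at 80 points, and it called 0 of 4403 unchanged sites. In a second simulation, of a broad loss, 80% of the sites over 30% methylated were lowered to 20% of their level. The test recovered 10.1% of falls of 20 to 40 points, 25.6% of falls of 40 to 60 points and 57.6% of falls of 60 to 80 points, with 0 of 2636 unchanged sites called. Its counts are therefore a lower limit for a broad loss and would miss most changes at a few sites.

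The share of the Uhrf1-/- loss regained was the rescue minus Uhrf1-/- over wild type minus Uhrf1-/-, in mean methylation over sites with a loss of at least 20 points. Sites were chosen on the libraries of one number, wild-type and Uhrf1-/- means were read from the libraries of the other number, and the 2 results were averaged. Shares by annotation class used group means over all sites of the class instead, with no choice by loss. For the plots and values by wild-type level, sites were sorted into bins of 10 points on one wild-type library and the wild-type mean was read from the other, in both directions. The overlap of losses was compared with 10000 permutations within bins of 10 points of wild-type level.

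Promoter, exon, intron, intergenic, CpG island and shore classes were the authors' own annotation of each site. The plan had been to find islands in a reference genome, which was not used here. Promoter values were means over sites within 1 kb of the nearest transcript start listed in the deposited tables. The tables name transcripts and no genes. A gene symbol was therefore assigned by position from a RefSeq gene table of the same mouse assembly. First came a gene with an end within 1 kb of the transcript start. This was the left end for a plus-strand transcript and the right end for a minus-strand one. Otherwise the only gene containing the start was taken. The gene's own strand was not compared, so a matched end is its 5′ end only where gene and transcript share a strand. Of 1560 transcript starts in the rescue table, 900 matched a gene end and 549 lay inside a gene. A further 43 were ambiguous and 68 matched none. For the knockdown, 1029 of 1803 matched a gene end, 650 lay inside a gene, 49 were ambiguous and 75 matched none. This gave 1333 and 1533 genes with a promoter value, which took together the sites near all starts assigned to a gene. A start inside a gene is often an internal start of a shorter transcript, so its value need not describe the main promoter.

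Named genes followed a rule fixed before the data were examined. For each comparison these were the protein-coding or listed genes with at least 3 promoter sites of at least 10 reads, of which the 10 largest falls and the 5 largest rises were taken. For Uhrf1-/- against wild type they also had to be called, with no overlap between the libraries of the groups. A few genes that met this rule are not reported here. Up to 4 measured members of each gene list were to be added; all measured members are given, with any number of sites. Uhrf1 and Kat8, the mouse gene of MOF, were to be added but had no site within 1 kb of a transcript start. The 9 lists, also fixed beforehand, were germline imprinted promoters, methylation-dependent germline genes, pluripotency genes, lineage transcription factors, trophoblast genes, two-cell stage genes, the DNA methylation machinery, housekeeping genes and fibroblast genes, the last as markers of another cell type. Of 205 listed genes, 201 had a symbol in the gene table, and few had promoter sites. A list with at least 3 measured members was compared with 10000 random promoter sets of its size matched on wild-type methylation.

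The alternatives were minimum differences of 10 and 30 points, minimum reads of 5 and 20, autosomes only, sites with 10 reads in every library, each replicate left out in turn, a replicate block, limma on a logit scale or with a pooled spread, means weighted by reads, medians, other choices of sites for the share regained, and other promoter windows and matching for the lists. No rescue of the knockdown and no expression data were analysed here.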

Results

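Methylation was measured at single cytosine sites in J1 mouse embryonic stem cells, a line grown in serum with leukemia inhibitory factor. UHRF1 binds hemimethylated DNA after replication and recruits the maintenance methyltransferase DNMT1, and MOF is a lysine acetyltransferase. The series title sets the question: how acetylation of UHRF1 by MOF bears on the upkeep of methylation across the genome. Cells without Uhrf1 (Uhrf1-/-, 2 libraries) were compared with wild-type cells (2 libraries). Single Uhrf1-/- colonies selected with hygromycin carried human UHRF1, either wild type (wild-type rescue, 1 library) or with 3 lysines changed to arginine (3KR rescue, 1 library, K667R, K668R and K670R). A further library came from cells with a stable knockdown of Mof. The 3 single-library groups have no replicate check, so no SD is given for them.

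In the rescue table the sites summed to 257860 and 445233 reads in the wild-type libraries, 615917 and 531050 in the Uhrf1-/- libraries, 668870 in the wild-type rescue and 393086 in the 3KR rescue. The median depth per site was 10 and 16 reads in wild type, 14 and 11 in Uhrf1-/-, 22 in the wild-type rescue and 14 in the 3KR rescue. In the knockdown table the Mof knockdown had 299507 reads in all and a median of 10 per site, beside 10 and 16 in wild type. At 10 reads, 1 read is worth 10 percentage points, so a value at one site is coarse and the values below are averages over sites.

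Loss of Uhrf1 lowered methylation throughout the sampled genome. Mean methylation over the 18189 sites was 49.1% ± 1.25 (SD, n = 2) in wild type and 9.59% ± 0.326 (SD, n = 2) in Uhrf1-/-, a difference of -39.6 percentage points (SE 0.878). The libraries within a group were 1.77 points apart in wild type and 0.461 apart in Uhrf1-/-. Sites over 80% methylated made up 32.4% ± 1.68 (SD, n = 2) of wild-type sites and 0.242% ± 0.0855 (SD, n = 2) of Uhrf1-/- sites. All 19 autosomes were lower, by mean differences between -45.8 and -28.5 points.

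**Figure D1:**
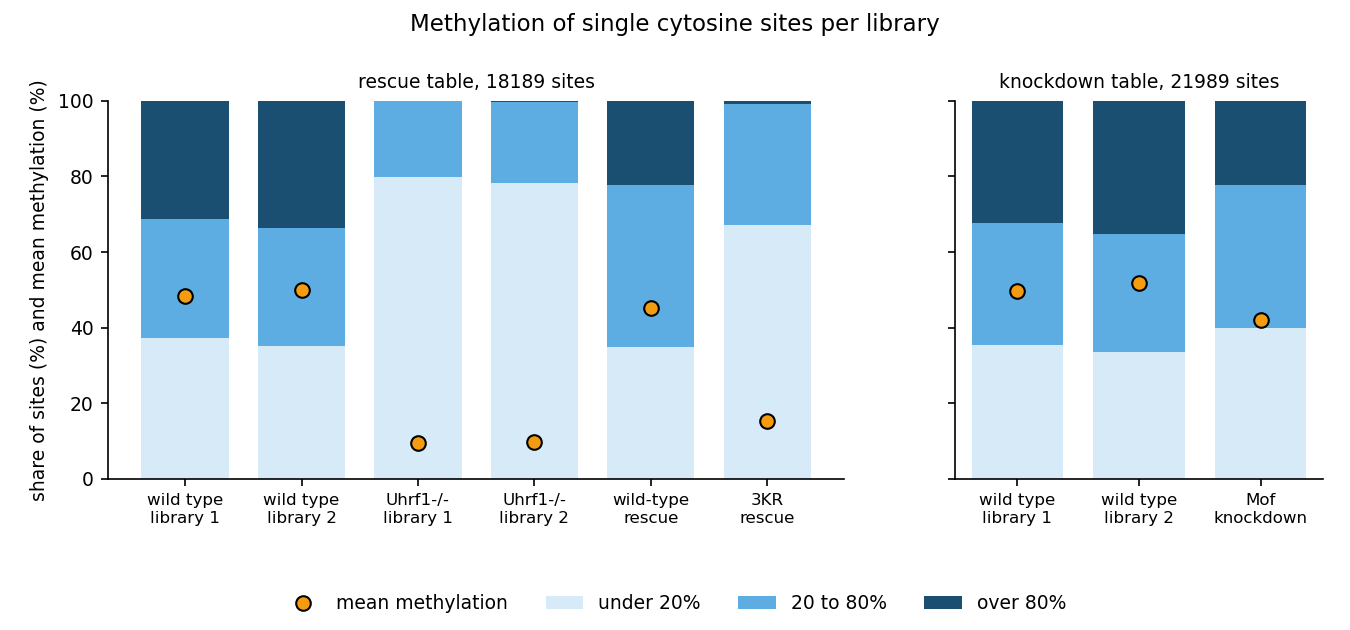
Share of sites (y axis, %) with methylation under 20%, from 20 to 80% and over 80% in each library (bars), with the mean methylation of the library (circles, same axis). Over 80% methylation is found at 31.2% and 33.6% of sites in the wild-type libraries of the rescue table and at 0.962% in the 3KR rescue; the means of the Uhrf1-/- libraries are 9.36% and 9.82%.

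Promoters, gene bodies and intergenic sites lost a like share of their methylation. Promoter sites went from 23.6% ± 1.05 to 4.48% ± 0.279, exons from 58.2% ± 1.45 to 11.2% ± 0.346, introns from 60.8% ± 1.30 to 12.2% ± 0.395 and intergenic sites from 61.3% ± 1.36 to 11.8% ± 0.281 (SD, n = 2 each). The level left in Uhrf1-/- was 19% of wild type at promoters, 19.3% in exons, 20% in introns and 19.2% between genes. CpG islands, which were nearly unmethylated in wild type at 4.07% ± 0.369, stood at 1.08% ± 0.0105 in Uhrf1-/- (SD, n = 2). Outside islands and shores the mean was 63.3% ± 1.38 in wild type and 12.4% ± 0.362 in Uhrf1-/- (SD, n = 2).

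**Figure D2:**
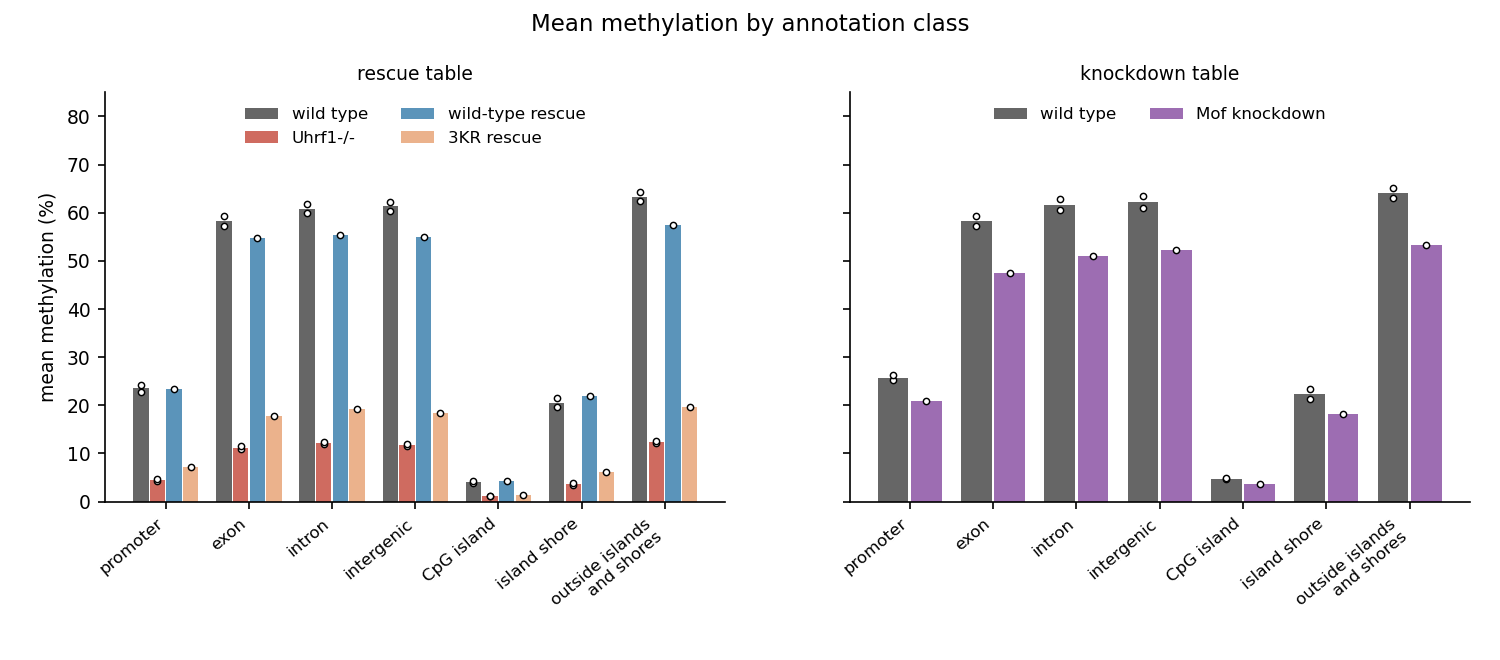
Mean methylation (y axis, %) by the authors' annotation classes (x axis). Bars are group means and white circles are single libraries; outside islands and shores the means are 63.3% in wild type, 12.4% in Uhrf1-/-, 57.4% in the wild-type rescue and 19.6% in the 3KR rescue, while wild type is at 64.1% and the Mof knockdown at 53.2% in the knockdown table.

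Among named promoters, the falls with the largest size were at Kctd10, which encodes an adaptor of a cullin ubiquitin ligase, Gip, the gene of an incretin hormone, and Myo15, a myosin of inner-ear hair cells. The 3 sites at Kctd10 (mm10, chromosome 5, 114364044 to 114364092) lie near a transcript start matched to an end of the gene. The gene's strand was not compared, so this end may be its 5′ or its 3′ end. Methylation there was 88.4% ± 0.0490 in wild type and 2.30% ± 3.25 in Uhrf1-/- (SD, n = 2, edgeR adjusted p = 0.00143). At Gip (chromosome 11, 96024883 to 96024942, 4 sites) it was 88.4% ± 2.81 and 5.36% ± 0.508 (SD, n = 2; edgeR adjusted p = 1.14e-05). At a start inside Myo15 (chromosome 11, 60479828 to 60479953, 6 sites) it was 86.9% ± 0.701 and 5.31% ± 6.27 (SD, n = 2, edgeR adjusted p = 1.14e-05). Falls between -79.0 and -69.6 points were called at starts inside Cacna1d, a calcium channel subunit, Strc, the inner-ear protein stereocilin, Setd1a, a histone methyltransferase, Usp22, a histone deubiquitinase, Med24, a Mediator subunit, and Emilin1, a glycoprotein of elastic fibers. These 9 promoters had 35 to 566 reads per library over 3 to 7 sites. No promoter with a rise met the rule.

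Germline genes that depend on methylation for silencing were represented by 4 of 30 members. Sycp1, of the synaptonemal complex (chromosome 3, 102936699 to 102936884, 4 sites), fell from 66.5% ± 1.19 to 1.67% ± 2.36 (SD, n = 2; edgeR adjusted p = 0.00317), and Meioc, a meiotic regulator (chromosome 11, 102664693 to 102664863, 9 sites), from 62.7% ± 0.0699 to 13.1% ± 2.66 (SD, n = 2; edgeR adjusted p = 0.021). Both passed over all promoters and when adjusted over the list alone. Smc1b was at 0% in both groups, and Tdrd1, with 1 site, was at 0% in wild type and 7.14% ± 10.1 in Uhrf1-/- (SD, n = 2). Of 3 imprinted promoters, 0 passed over all promoters and 0 adjusted over the list alone. Mest measured 50.8% ± 8.98 in wild type and 17.5% ± 9 in Uhrf1-/- (SD, n = 2; edgeR adjusted p = 0.319), Nnat 50.3% ± 13.8 and 10.5% ± 14.9 at 1 site (SD, n = 2; edgeR adjusted p = 0.328), and Inpp5f 0% in both. Lineage transcription factors had 6 measured members and 0 calls. Pax7, Olig2, Lhx2, Six3 and Neurog1 were between 0% and 1.67% in both groups, and Hoxa9 measured 33.3% in each wild-type library (6 reads each) and 0% in each Uhrf1-/- library (5 and 12 reads) at 1 site. The pluripotency genes Sox2 (3.12% ± 4.42 in wild type, SD, n = 2) and Nr5a2 (0%) and the fibroblast gene Col3a1 (22.2% ± 31.4 in wild type and 37.5% ± 53.0 in Uhrf1-/-, SD, n = 2, 1 site) were not called either. The median list difference lay at percentile 59.5 of matched random promoter sets for the germline genes, 89.6 for the imprinted promoters and 45.5 for the lineage factors. The lists had 3 to 6 measured members, some at or near 0% in wild type with no methylation to lose. These percentiles therefore cannot decide whether a list stood apart. No trophoblast, two-cell stage, methylation machinery or housekeeping gene had a promoter site in this table.

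Per site, edgeR called 1488 of 4603 sites lower (32.3%) and 0 higher in Uhrf1-/-. Of the 4603 sites, 3917 had both methylated and unmethylated reads and could be tested. At an unadjusted p under 0.05 and any size of difference, 2005 sites were lower and 15 higher, and limma called 1349 lower and 3 higher on the methylation level and 625 lower and 2 higher on a logit scale. By size alone, 2511 sites were at least 20 points lower and 3 were higher. Over all promoters, with any number of sites of at least 5 reads, 325 of 1333 genes were called lower and 0 higher. Of these genes 1192 could be tested. With at least 3 sites of at least 10 reads, 60 of 247 genes were called lower and 0 higher, and 231 could be tested. The authors' deposited table lists 11144 of 18189 sites with a q-value under 0.05 and a difference of at least 20 points in the direction of loss, and 49 in the direction of gain. The edgeR count of single sites depends on the libraries: it was 39 without wild-type library 1, 27 without wild-type library 2, 0 without Uhrf1-/- library 1 (1657 lower at an unadjusted p under 0.05) and 720 without Uhrf1-/- library 2. The mean difference without each library stayed between -40.4 and -38.7 points.

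The Uhrf1-/- colony that carried wild-type human UHRF1 had a mean methylation close to, but below, the wild-type level. The wild-type rescue had a mean of 45.3%, 35.7 points above Uhrf1-/- (SE 0.611) and -3.88 points from wild type (SE 0.413). Sites over 80% methylated made up 22.3% of its sites, beside 32.4% ± 1.68 (SD, n = 2) in wild type. All 19 autosomes were higher than in Uhrf1-/-, by 26.9 to 40.9 points, and lower than in wild type, by mean differences between -6.29 and -1.37 points. Against the wild-type mean, 1262 of 7430 sites were at least 20 points lower and 636 higher. Over sites that had lost at least 20 points, the wild-type rescue regained 86.9% of the loss (SE 0.759), 85% and 88.8% with the sites chosen on either set of libraries.

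Class shares were taken over all sites of a class, without choosing sites by loss. Over all sites of the rescue table the regained share was 90.2%. Promoters measured 23.3% in the rescue and regained 98.8% of the class loss, and island shores 22.0% and 108.6%. The share was 92.8% in exons, 88.8% in introns and 87.1% between genes. Weakly methylated sites, where the rescue lay above wild type, enter these shares. They therefore do not show how complete the return was at the sites that lost methylation. Kctd10 measured 100% in the wild-type rescue (38 reads), Ccl22, a chemokine gene (chromosome 8, 94745037 to 94745125, 4 sites), 85.4% against 1.56% ± 2.21 in Uhrf1-/- (SD, n = 2), and a start inside Mtus1, a microtubule-associated protein (chromosome 8, 40999490 to 40999560, 4 sites), 75.9% against 0% in both Uhrf1-/- libraries. A start inside Med24 measured 92.1%. Sycp1 reached 38.8% and Meioc 63.7%, beside 66.5% and 62.7% in wild type, and the imprinted Mest and Nnat measured 55.7% and 52.9%. The germline list's median gain was 18.5 points, at percentile 31.6 of matched promoters, and the imprinted list's 38.2 points, at percentile 61.6.

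Promoters that were lower in the wild-type rescue than in Uhrf1-/- differed by little. The largest difference was at a start inside Pde4dip, which encodes a centrosomal scaffold (chromosome 3, 97867722 to 97867780, 3 sites), at 0% against 11.1% ± 3.14 (SD, n = 2). The next were H4c14, a histone gene, at 0.396% against 4.33% ± 1.59, Mmd at 1.01% against 4.85% ± 0.125 and Vcl, the focal adhesion protein vinculin, at 0% against 3.43% ± 0.808 (SD, n = 2 each). Differences at Fa2h, Zdhhc18, Atg12, Sbf1, Shc1 and Rnf112 were between -3.42 and -2.02 points.

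By size, 4999 of 8193 sites (61.0%) were at least 20 points higher in the wild-type rescue than the Uhrf1-/- mean and 10 were lower. Against single Uhrf1-/- libraries, 7172 of 11762 were higher and 60 lower (library 1) and 6034 of 9807 higher and 51 lower (library 2). Between the 2 Uhrf1-/- libraries 788 of 9373 sites were at least 20 points higher and 708 lower, and between the wild-type libraries 1065 of 7991 were higher and 725 lower. Against wild type, the authors' deposited table lists 2450 sites lower and 1189 higher in the wild-type rescue. With 1 selected colony, the clone and the transgene cannot be separated.

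Methylation was far lower in the colony with the 3 lysines changed to arginine than in the colony with wild-type UHRF1. The 3KR rescue had a mean of 15.2%, 5.57 points above Uhrf1-/- (SE 0.192) and -30.1 points from the wild-type rescue (SE 0.545). Between medians, the 3KR rescue was 0.318 points above Uhrf1-/- and -49.7 points from the wild-type rescue. Only 0.962% of its sites were over 80% methylated. It regained 14.4% of the Uhrf1-/- loss (SE 0.463), which is 72.5 points less than the wild-type rescue (SE 0.833). All 19 autosomes were lower than in the wild-type rescue, by mean differences between -33.8 and -22.9 points, and all 19 were higher than in Uhrf1-/-, by 4 to 7.52 points.

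Every annotation class showed the same order. Promoter sites measured 7.21% in the 3KR rescue, beside 23.3% in the wild-type rescue and 4.48% ± 0.279 in Uhrf1-/- (SD, n = 2). They regained 14.3% of the class loss, taken over all sites of the class without choosing sites by loss. On this measure introns, at 19.3%, regained 14.6%, and intergenic sites, at 18.4%, regained 13.4%. The differences from the wild-type rescue with the largest size were at starts inside Lmnb2, a nuclear lamin (chromosome 10, 80906110 to 80906117, 3 sites), with 0% of 35 reads methylated against 93.7% in the wild-type rescue, at Gm15455 (chromosome 1, 33838443 to 33838557, 5 sites), with 4.10% against 84%, and inside Ccdc28b (chromosome 4, 129620709 to 129620841, 3 sites), with 10% against 88.4%. With 35 reads the Wilson 95% interval at Lmnb2 reached 9.89%. Starts inside the mucin Muc1, the NF-κB regulator Nfkbiz, the connexin gene Gjb6, the transcription factor Ebf3, the ubiquitin ligase Peli3, the centrosomal Sdccag8 and the translation factor Eif4g1 differed by between -76.8 and -66.6 points. Some were higher in the wild-type rescue than in wild type, with the widest gaps at Sdccag8 (80.3% against 33.8% ± 7.79) and Muc1 (93.5% against 59.6% ± 0.412, SD, n = 2 each). These promoters were chosen for a large gap between the rescues, which favors high values in the wild-type rescue library. Their excess over wild type therefore cannot be told from that choice.

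Methylated germline and imprinted promoters were lower in the 3KR rescue than in the wild-type rescue, and only Meioc was above Uhrf1-/-. Sycp1 measured 0% in the 3KR rescue against 38.8% in the wild-type rescue, and Meioc 23.3% against 63.7%. Mest measured 11.1% and Nnat 10%, against 55.7% and 52.9%. The median difference was -19.4 points for the germline list (percentile 54.2 of matched promoters), -42.9 points for the imprinted list (percentile 18.4) and -4.40 points for the lineage factors (percentile 17.4). With so few members, some near 0% in wild type, these percentiles cannot decide whether a list stood apart. Among promoters with at least 3 sites of at least 10 reads, the 4 reported above the wild-type rescue differed by under 10 points. Esr2, an estrogen receptor gene, measured 9.09% against 0%, St6galnac2 18.5% against 10.5%, Alox12 5.95% against 0% and Rbm47 5.33% against 0%.

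Against Uhrf1-/-, the 3KR rescue was higher at starts inside Strc (40.2% against 8.57% ± 0.956), Ltbp3, a latent growth factor binding protein (28.6% against 1.28% ± 1.81), Med24 (43.7% against 16.6% ± 5.45), Ftsj3 (33.3% against 6.74% ± 9.53) and Gm272 (22.2% against 1.96% ± 2.77; SD, n = 2 each). At Kctd10 it measured 58.3% over 24 reads, with a Wilson 95% interval of 38.8% to 75.5% on the pooled reads. It was lower than Uhrf1-/- at Top2a, a DNA topoisomerase (0% against 21.6% ± 16.6, SD, n = 2), where the Uhrf1-/- libraries lay far apart. The other 9 of the 10 largest differences below Uhrf1-/- were between -12.8 and -6.32 points, at Gjb6, Lss, Lypla2, Gm15455, Rnf112, Il15ra, Csmd3, Gart and Trio.

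By size, 6786 of 11900 sites (57.0%) were at least 20 points lower in the 3KR rescue than in the wild-type rescue and 115 were higher. Fisher's exact test on the reads, which compares these 2 libraries and not the conditions, called 5467 sites lower and 29 higher; between the wild-type libraries it called 36 lower and 84 higher of 7991. With the spread of the replicated groups, limma called 1102 sites lower and 19 higher and edgeR 1 lower and 0 higher (1533 lower and 12 higher at an unadjusted p under 0.05), so the site count rests on the size rule. Against the Uhrf1-/- mean, 1149 of 7287 sites (15.8%) were at least 20 points higher and 204 (2.80%) lower. Against single libraries, 1757 of 10108 sites were higher and 508 lower (library 1) and 1483 of 8559 higher and 430 lower (library 2), beside 788 of 9373 higher and 708 lower between the 2 Uhrf1-/- libraries. Against wild type, the authors' deposited table lists 9736 sites lower and 170 higher in the 3KR rescue. With 1 colony per rescue and no transgene level analysed here, the lysine changes cannot be separated from the clone or the transgene level.

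**Figure D3:**
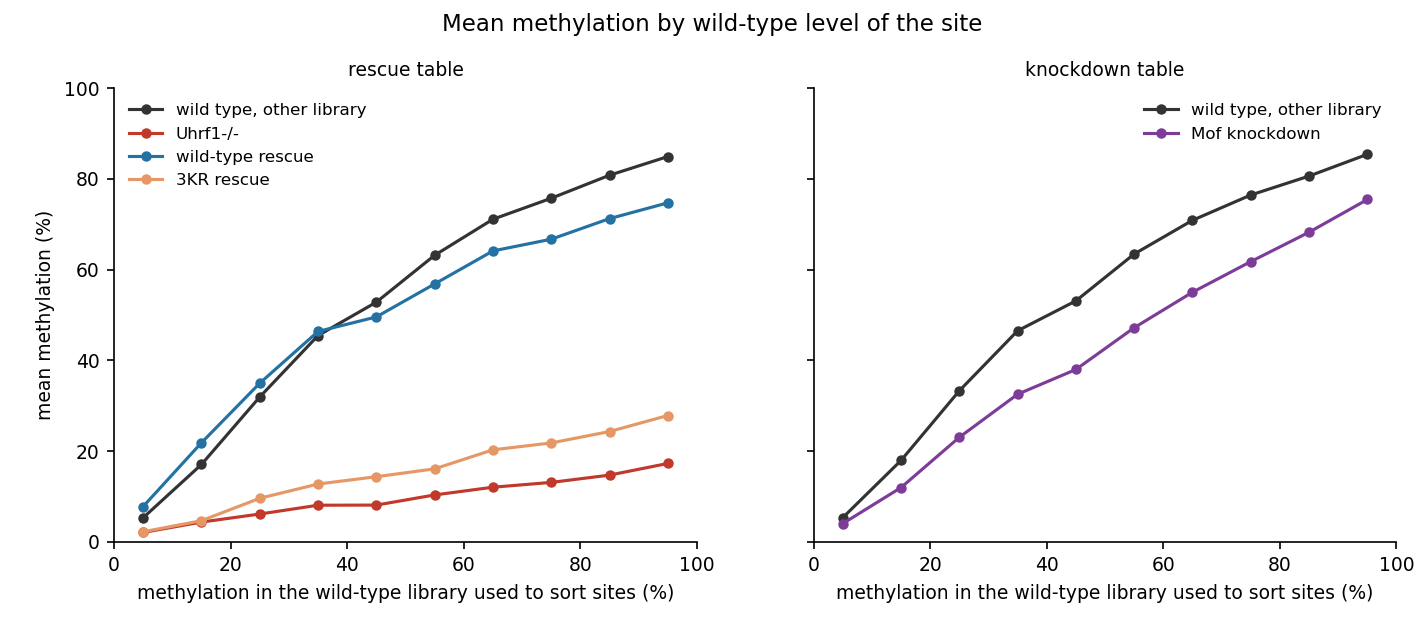
Mean methylation (y axis, %) of sites sorted by their level in one wild-type library (x axis, %, bins of 10 points), with wild type read from the other library and both directions averaged. At sites of 90 to 100% the means are 84.9% in wild type, 74.7% in the wild-type rescue, 27.8% in the 3KR rescue and 17.3% in Uhrf1-/-; in the knockdown table they are 85.4% in wild type and 75.5% in the Mof knockdown.

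The rescues also differed from wild type by site level. At sites of 0 to 10% in one wild-type library the wild-type rescue was 2.47 points above the other wild-type library (SE 0.261), at sites of 10 to 20% it was 4.79 points above (SE 0.757), and at sites of 90 to 100% it differed by -10.2 points (SE 0.578). The 3KR rescue was close to Uhrf1-/- at weakly methylated sites, with 4.65% against 4.35% at sites of 10 to 20%, and above it at strongly methylated sites, with 27.8% against 17.3% at sites of 90 to 100%.

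Knockdown of Mof went with a smaller and uneven loss. Over the 21989 sites of the knockdown table, mean methylation was 50.7% ± 1.40 (SD, n = 2) in wild type and 42.0% in the knockdown, a difference of -8.74 points (SE 0.360), where the wild-type libraries were 1.97 points apart. The knockdown was below each wild-type library, by -7.75 and -9.73 points, and below their mean on all 19 autosomes, by -10.2 to -3.76 points. Sites over 80% methylated made up 22.4% of its sites, beside 33.8% ± 2.05 (SD, n = 2) in wild type. The difference of medians was -24.0 points. Weighted by reads, the difference was -2.92 points, and the pooled share of 42.5% in the knockdown lay between 40.4% and 50.5% in the wild-type libraries.

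Exons differed by -10.8 points, introns by -10.6, intergenic sites by -9.92 and promoter sites by -4.91, which left 81.5%, 82.7%, 84.1% and 80.9% of the wild-type level. The difference was widest at intermediate sites, with -16.2 points (SE 0.551) at sites of 50 to 60% in wild type, against -9.96 points (SE 0.383) at sites of 90 to 100%. Among promoters with at least 3 sites of 10 reads, the largest difference was at a start inside Slc20a2, a phosphate transporter (chromosome 8, 22506629 to 22506772, 4 sites), with 8.33% against 69.3% ± 17.1 (SD, n = 2). Others were Iqank1 (9.52% against 48.0% ± 7.02), sites in Kmt2b, a histone methyltransferase (40.4% against 76.2% ± 14.2), and Dbn1, the actin-binding drebrin (7.33% against 42.6% ± 7.11, SD, n = 2 each). The Kmt2b sites (chromosome 7, 30574263 to 30584476) and the Dbn1 sites (chromosome 13, 55483557 to 55488470) lie near separate transcript starts. Each of these values is a mean over those starts and not of a single promoter. Nnat (3 sites of at least 10 reads), Arhgap27, Usp22, Bpi and Dkkl1 differed by between -33.3 and -32.3 points. Of these, Usp22 was also among the largest falls in Uhrf1-/-.

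**Figure D4:**
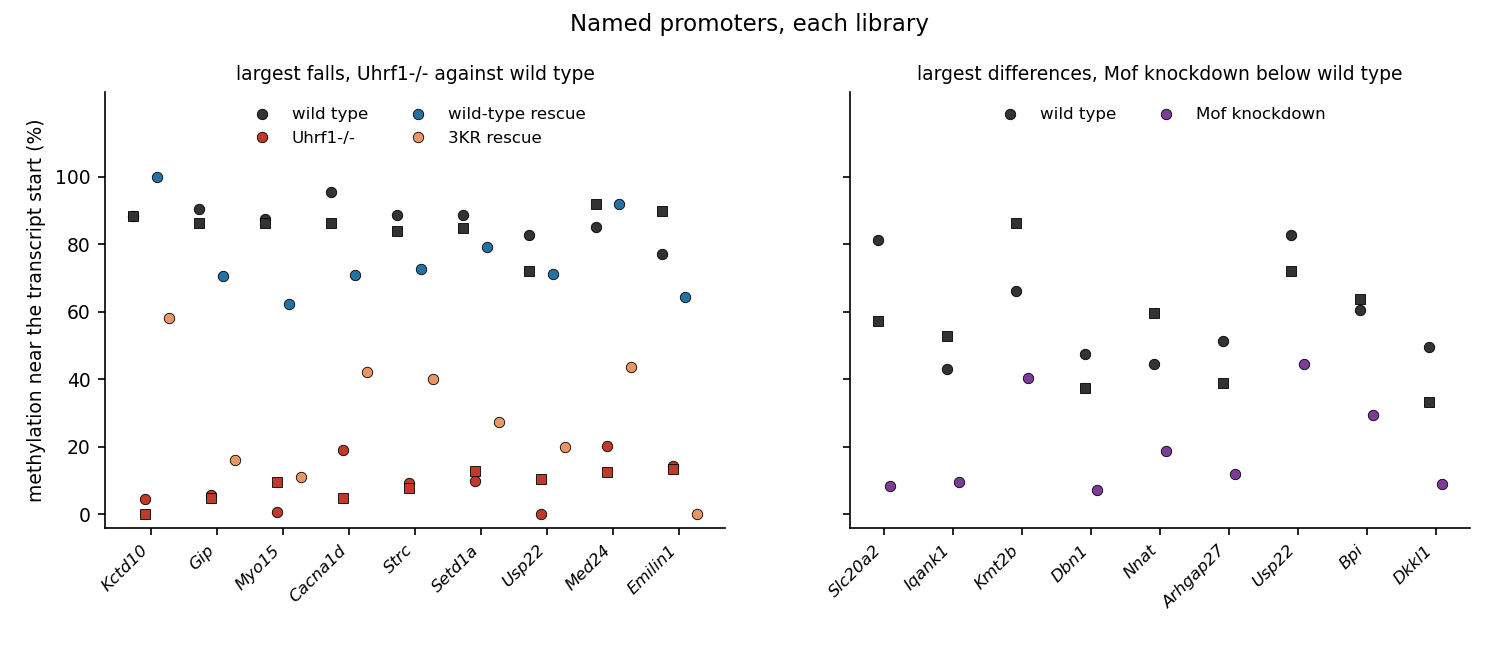
Methylation near the transcript start (y axis, %) of 9 promoters with the largest falls in Uhrf1-/- (left) and of 9 with the largest differences below wild type in the Mof knockdown (right), 1 point per library; circles are library 1 and squares library 2 of a group. At Kctd10 the wild-type libraries are at 88.5% and 88.4% and the 3KR rescue at 58.3%. At Slc20a2 the knockdown is at 8.33%. Values at Kmt2b and Dbn1 are means over separate transcript starts.

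Sycp1 measured 29.2% in the knockdown, beside 66.5% ± 1.19 in wild type, and Meioc 50.3% beside 62.7% ± 0.0699 (SD, n = 2). Brdt, a testis bromodomain gene, measured 0% beside 12.2% ± 17.3, and Tdrd1 0% in both. Of imprinted genes, Nnat measured 29.1% beside 49.1% ± 10.4 over all 4 sites, and Gnas 83.3% beside 80.7% ± 13.1 (SD, n = 2 each). The added Nnat site brings the difference there from -33.3 to -19.96 points. Meg3, an imprinted noncoding RNA, differed by -15.9 points from 65.8% ± 0.138 (SD, n = 2) over 9 sites. Among lineage factors Pax6 measured 64.2% beside 77.3% ± 4.85 (SD, n = 2), and Pax7, Gata4, Neurog1, Olig2, Lhx2 and Six3 were between 0% and 1.45% in both groups. The pluripotency genes Sox2, Esrrb and Nr5a2 measured 0% in the knockdown and up to 1.25% in wild type. Usp7, of the methylation machinery, measured 70% beside 78.5% ± 9.19, and the fibroblast gene Thy1 14.3% beside 79.5% ± 11.4 at 1 site (SD, n = 2 each). No housekeeping, trophoblast or two-cell stage gene was measured. List medians lay at percentiles 22.3 (germline), 44.2 (imprinted), 62.7 (lineage) and 57.9 (pluripotency) of matched promoters. Differences in the direction of gain were seen at starts inside Gng8 (20% beside 4.04% ± 0.577), Maneal (14.5 points higher), Coq8a (33.3% beside 23.3% ± 14.1) and Pik3cd (8% beside 2.38% ± 3.37), and at Manea (7.41% beside 0%; SD, n = 2 each).

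By size, 1415 of 6679 sites (21.2%) were at least 20 points lower in the knockdown than the wild-type mean and 290 (4.34%) higher. Against single libraries, 21.7% were lower and 7.54% higher (library 1) and 26.7% lower and 5.58% higher (library 2), beside 13.9% higher and 8.91% lower between the wild-type libraries. Fisher's exact test, which compares libraries and not conditions, called 252 sites lower and 71 higher of 7399 against wild-type library 1. Against library 2 it called 874 lower and 92 higher of 10204. Between the wild-type libraries it called 39 lower and 124 higher of 9600, so the higher calls in the knockdown were no more frequent than between those libraries. With the spread of the wild-type libraries, limma called 158 sites lower and 53 higher, and edgeR called 0 in either direction (146 lower and 64 higher at an unadjusted p under 0.05). The authors' deposited table lists 2694 sites lower and 436 higher of 21989. With 1 library, a difference between cultures cannot be separated from the knockdown.

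Sites that were lower in the knockdown were compared with those lower in the 3KR rescue than in the wild-type rescue, 2 comparisons that share no library. Of 4272 shared sites, 846 were at least 20 points lower in the knockdown, 2225 in the 3KR rescue and 703 in both. Independent lists would share 440.6 sites, but both losses need methylation to start from. Permutation within bins of wild-type level gave 709.2 on average, with 95% of permutations between 693 and 725 (two-sided permutation p = 0.474 for 10000 permutations over sites, which are not independent). The knockdown loss and the bins use the same wild-type reads. Within a bin, a site with a wild-type value too high by chance has less true methylation to lose. This can lower the overlap, so the count cannot decide whether the losses share sites beyond the wild-type level. The overlap was slightly under expectation at a minimum difference of 10 points (1210 against 1226.9 sites, permutation p = 0.028). In a check chosen after the data were seen, it was also under expectation at a minimum of 5 reads (2457 against 2495.3, permutation p = 0.0234). Spearman's rho of the differences across sites was 0.264, and its mean within the bins was -0.0792.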

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

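Chosen after the data were seen were limma on the level, edgeR with pooled or wild-type spread, means and regained shares at 10 reads in every library, and the overlaps with other bins or 5 reads.

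No result reversed. Of the alternatives to the results that answer a comparison, 70 left the result the same (within the replicate spread, 1.5 times a count, or the same side of a threshold) and 47 moved. The 70 include every alternative for the gene lists. Some of those percentiles moved widely, as from 89.6 to 26.8 for the imprinted list in Uhrf1-/- without matching on wild-type level. The list percentiles cannot decide whether a list stood apart, so their label of same is no sign of a stable result. The other 2 alternatives, both of the overlap of losses, passed to a permutation p under 0.05, below expectation. Minimum reads changed how many sites could be counted, and the counts in the main direction changed with it. The share of sites called lower in Uhrf1-/- changed too, from 32.3% at 10 reads to 23.5% at 5 and 22.9% at 20. At 5 reads the counts were 4275 (Uhrf1-/- lower), 11041 (wild-type rescue higher), 3327 (3KR rescue higher than Uhrf1-/-) and 5642 (Mof knockdown lower). At 20 reads they were 119, 470, 107 and 187. For 3KR rescue below wild-type rescue the counts were 10105 at 5 reads and 2690 at 20. With 10 reads in every library the counts for the wild-type rescue, the 3KR rescue over Uhrf1-/- and the 3KR rescue below the wild-type rescue were 2087, 530 and 1946. At 10 and 30 points the 3KR rescue was higher than Uhrf1-/- at 2020 and 603 sites and lower at 660 and 65, and the knockdown lower at 2271 and 856 and higher at 736 and 123. The logit scale in limma called 625 sites in Uhrf1-/-. With a borrowed spread, limma called 1102 sites and edgeR 1 for the 3KR rescue below the wild-type rescue, and limma 158 and edgeR 0 for the knockdown; the cause was not tested.

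Weighted by reads, mean differences were -37.3 (Uhrf1-/-), 37.5 (wild-type rescue), 8.18 (3KR rescue over Uhrf1-/-) and -2.92 points (knockdown). Medians gave -55.0, 50, 0.318, -49.7 (3KR rescue below the wild-type rescue) and -24.0. Sites with 10 reads in every library gave -34.9 (Uhrf1-/-), 31.3 (wild-type rescue) and -26.4 points (between the rescues). The regained share was 90.2% over all sites for the wild-type rescue and 19.96% weighted by reads for the 3KR rescue. The overlap of losses was 98.6% of that expected at 10 points (permutation p = 0.028) and 98.5% at 5 reads (permutation p = 0.0234), so slightly under expectation in both. The bins share wild-type reads with the knockdown loss, which can lower both values. The cause was not tested.

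Leaving out 1 library gave 0 to 720 lower sites in Uhrf1-/-, with the lone library assumed to vary like the others, 6034 to 7172 higher sites in the wild-type rescue, 1483 to 1757 in the 3KR rescue and 1606 to 2726 lower sites in the knockdown. Mean differences were between -40.4 and -38.7, 35.4 and 35.9, 5.34 and 5.80, and -9.73 and -7.75 points. Regained shares were between 81.6% and 87.3% for the wild-type rescue and 13.4% and 16.7% for the 3KR rescue. For these shares, a group left with 1 library had sites chosen and read on that same library. That choice alone can shift the shares. A replicate block on the library number gave 708 lower sites in Uhrf1-/-; the labels do not say that a number marks a shared day, and the same-numbered deviations had a correlation of 0.00269 across sites, so the numbers are not taken as pairs. Means over all sites of a library and matching of single sites by overlap give no other value, since every site is measured in every library.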

Other observations

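The account of residual methylation in Uhrf1-/- cells, the conversion tests of the knockdown and of the wild-type rescue and the test of a mixture with the rescue pattern were chosen after the results were seen.

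Some sites kept methylation without Uhrf1, and did so in both libraries. On average 345.5 sites with at least 10 reads were at 50% or more in one Uhrf1-/- library, and these measured 31.1% in the other Uhrf1-/- library (jackknife SE 1.10). Other sites with the same wild-type level measured 14.8% there (SE 0.245). The same sites measured 41.8% in the 3KR rescue (SE 1.31), against 24.4% at matched sites (SE 0.389), and 77.9% in the wild-type rescue. Of them 50.1% lay in introns and 96.5% outside islands and shores, against 34.4% and 70.3% of all sites; their location was not compared with that of other methylated sites. No explanation was tested.

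The Mof knockdown lay below both wild-type libraries in the unweighted mean over sites, -8.74 points from their mean; the difference was -24.0 points between medians and -2.92 points weighted by reads, where the pooled share lay between those of the wild-type libraries. The depth test argues against lower depth as the cause: at sites with at least 20 knockdown reads the difference was -6.95 points (SE 1.27), still beyond the 1.97 points between the wild-type libraries. More complete bisulfite conversion was judged from mitochondrial reads as a mostly unmethylated control. Of these, 3.25% were methylated in the knockdown (exact 95% interval 2.60% to 4%, 2618 reads) and 0.825% and 0.626% in wild type, which goes against it. CpG islands, nearly unmethylated in wild type, went the other way, at 3.57% in the knockdown and 4.76% ± 0.144 (SD, n = 2) in wild type. Because these values disagree, conversion is not settled. The knockdown itself and a difference between cultures or clones cannot be told apart, because there is 1 knockdown library. A part of maintenance methylation that needs MOF may account for the loss; this is a hypothesis, which further knockdown libraries and a rescue of the knockdown would test.

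The 3KR rescue lay above Uhrf1-/- by 5.57 points in the unweighted mean, 0.318 points between medians and 8.18 points weighted by reads. A fixed share of cells or reads with the wild-type rescue pattern would give the same gain, relative to that rescue, at every wild-type level, but the gain was 11.7% (SE 0.936) at sites of 10 to 50% and 18% (SE 0.611) at sites over 80%, a difference of -6.35 points (SE 1.02). A mixture with the wild-type pattern is argued against less strongly: with sites chosen on one wild-type library and wild type read from the other, the gain relative to wild type was 17.4% (SE 1.43) at sites where the wild-type rescue exceeded wild type by at least 30 points and 14.2% (SE 0.477) at other sites, a difference of 3.18 points (SE 1.51), just over 2 SE. Remaining activity of the changed UHRF1 could leave such a partial level and was not tested, and with 1 colony a property of the clone stays open.

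The wild-type rescue lay above wild type at weakly methylated sites and below it at strongly methylated ones. Chance in choosing low wild-type values would vanish when wild type is read from the library not used to choose, but at sites of 10 to 30% the rescue was still 3.85 points above (SE 0.763). Incomplete conversion in the rescue library would raise its mitochondrial share by a like amount, and that share exceeded wild type by 0.245 points (binomial SE of the rescue share alone 0.155, with reads taken as independent). These values argue against both technical explanations; a hypothesis is that methylation may be set anew with less regard to the former pattern, and the level of the transgene or the history of the colony could also matter. None of these was tested, and further rescue colonies with measured transgene levels would be needed.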
